A study of Pinus pinaster with 24 samples.

How the data were processed

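RNA from roots, stem, needles and cotyledons of sulfur-starved maritime pine seedlings was sequenced in 24 libraries, 3 per organ and treatment. Per the labels' protocols, poly(A) RNA was enriched with oligo(dT) beads, copied with random hexamers and sequenced as paired reads of 150 bp on an Illumina NovaSeq. The library kit is not described as keeping strand, so overlapping transcripts on opposite strands cannot be told apart. The submitters' processing notes name bcl2fastq and BWA without versions. The counting tool, the reference transcripts, the scaling method and any filter are not given in the sources used here.

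The deposited table holds a level for 67271 transcript features in each library. It is presented as CPM, but the deposited columns do not sum to the total that plain CPM would give, so the values were treated as a signal, CPM of a library size scaled by the authors. The implied scaling factors run from 0.877 to 1.22 and are alike within an organ: 1.20 to 1.22 in roots, 1.07 to 1.10 in stem, 0.877 to 0.984 in needles and 0.926 to 0.958 in cotyledons. Levels compared between organs rest on this scaling. In the deposited signal every value is a whole multiple of its library's smallest step, within a tolerance of 0.01 of a step (100% of values), so the reads behind each value could be recovered. In needle control 2 the step lies close to 0.01, where rounding could give such steps, but 2.78% of its values above 0 are multiples of 0.01 itself within that tolerance, against 100% for its own step. Totals were 92664463 to 104403811 reads in roots, 95097766 to 100891286 in stem, 97443848 to 134863358 in needles and 97066476 to 195881948 in cotyledons. Among values of 1 to 20 reads, 57.9 to 69.9% were even, so both mates of a pair may have been counted, and intervals or floors in reads cover counting error only. A level of 3 reads is 0.0165 to 0.0351 normalized CPM, depending on the library. Each listed feature reaches a value of 1 in at least 3 libraries. Many features with neighbouring numbers have correlated levels, and reads shared between close copies could have been split or counted more than once by the authors' counting, so single features are uncertain in that respect.

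Groups and replicate numbers were taken from the labels. Pairs of libraries of a group differed by a chi-square of 11.0 to 68.8 per feature on recovered reads, above sampling noise, so none was treated as a repeat of another. The labels call the pools biological replicates, and p-values measure the spread between these 3 pools a treatment.

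The tests, the rule for named features and most alternatives were fixed before the data were examined; those added later are named in the closing section. In each organ, features with a value of at least 1 in at least 3 of the 6 libraries were tested for sulfate against control with limma (lmFit, and eBayes with trend and robust options) on log2(value + 0.5), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale and understate the change of low features. The average over organs was tested on means of the 4 organs of each treatment and replicate number. Differences between organs were tested in a fit of 24 libraries, as an F test of the interaction and for 6 pairs of organs, over the 47248 features that pass the filter in every organ. Organ contrasts used the 12 control libraries and set each organ against the mean of the other 3. Overlaps used a one-sided Fisher's exact test per pair and direction. The rule for naming took, for each comparison, the 2 features with the largest rise and the 2 with the largest fall among those with an adjusted p under 0.05, no overlap between the 3 sulfate and 3 control values and a mean of at least 2 in the higher group. Chance gives no overlap in 10% of 3 against 3 comparisons. A feature that 2 comparisons name counts in both. The identifiers are not paired with gene names in the files, so the planned tests of gene lists (camera and fry) were not run, and no genome or annotation was used here.

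Because the values are not counts as deposited, limma gave the main results, and edgeR's quasi-likelihood test on the recovered reads was an alternative. The plan had assumed plain CPM, and the scaled values need the same test. Other alternatives were pseudocounts of 0.1 and 2, no filter and a minimum of 5, rescaling by the median ratio, a fit over all 24 libraries, the replicate number as a block, a fold threshold and leaving out each library. Runs of neighbouring identifiers were defined as numbers at most 2 apart with a Pearson correlation over 0.8 across the 24 libraries. The tools were R 4.3.3, limma 3.58.1 and edgeR 4.0.16, with figures drawn in Python 3.11.15 with matplotlib 3.10.9.

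The fits were tested on simulated reads drawn from the organ means and the totals of the real libraries. The spread was that estimated per feature in each organ, or the organ's common value for features under the filter. In the simulation 200 features changed in all organs and 200 others in roots alone. The root contrast in control organs was simulated apart, from means over all 24 libraries and with a single spread for all features. For sulfate against control in roots (60278 simulated features tested), 91 of 100 features changed 2-fold and 99 of 100 changed 4-fold were recovered by limma. The like numbers were 67 and 95 in stem (58477 tested), 61 and 96 in needles (58640) and 62 and 93 in cotyledons (54831). For the average over organs 97 of 100 were recovered at either size (47061 tested), for the interaction F test 187 of 200 changed 4-fold in roots alone, and for the root contrast in control organs 90 of 100 at 2-fold (65420 tested). False calls made up 11.3% of simulated limma calls in roots, 14.7% in stem, 16.9% in needles, 13.9% in cotyledons, 10.8% for the average and 21.1% for the F test, above the nominal 5%. Without the trend and robust options the share was 4.48% in roots, 9.58% in stem, 8.51% in needles and 10.4% in cotyledons, and the 2-fold features recovered were 87, 56, 33 and 35 of 100. These shares are of all simulated calls and depend on the number of features changed in the simulation. For calls close to the threshold the share was not measured and may be higher.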

Results

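RNA was sequenced from 4-month-old seedlings of maritime pine (Pinus pinaster), a conifer whose young plants carry cotyledons, the seed leaves, alongside the later needles. Sulfate is the main form in which plants take up sulfur, which they build into cysteine, methionine and glutathione. From 1 month after germination the seedlings were watered weekly for 3 months with 0.3 mM KNO3, a feed without sulfur. They were then given either 1 mM KCl as control or 0.5 mM K2SO4, and roots, stem, needles and cotyledons were sampled 24 h later. Each of the 8 groups held 3 libraries, and each library came from a pool of 13 to 14 seedlings, which the labels call biological replicates. Levels of 67271 transcript features were given in each of the 24 libraries as CPM of a scaled library size (normalized CPM below). Between 92664463 and 195881948 reads stood behind a library. Cotyledon control 1 (195881948 reads) and needle control 1 (134863358 reads) lay above the others, which reached at most 104403811. The feature identifiers are not paired with gene names in the files, so the features named here carry no known function. Because no names were paired, none of the gene lists chosen for sulfur metabolism or other processes could be matched.

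Organ set the largest differences between libraries. Spearman correlation across features was 0.964 to 0.990 within a group, 0.955 to 0.982 between treatments of an organ and 0.527 to 0.906 between organs. Features are not independent replicates, so these values describe the libraries only. The first 3 principal components held 66.9%, 15.8% and 10.02% of the variance and parted the organs. The fourth held 1.62% and parted the treatments in every organ, with scores of 9.76 to 55.4 in the 12 control libraries and at most -13.3 in the 12 sulfate libraries. The 10 most abundant features took 2.18 to 4.99% of the reads of a library.

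**Figure D1:**
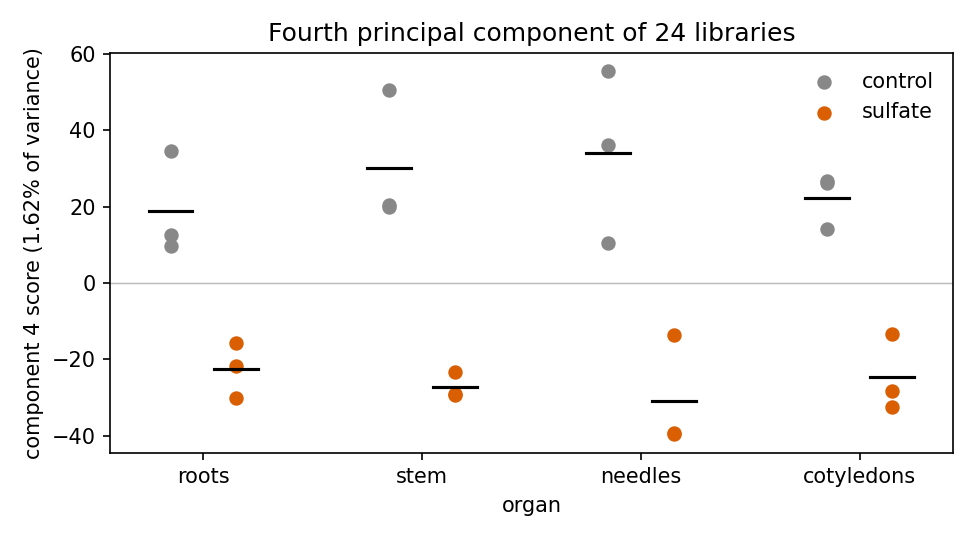
Score of each of the 24 libraries on the fourth principal component of log2(normalized CPM + 0.5), by organ and treatment (arbitrary units; bars are means of 3 libraries). Control libraries score 9.76 or more and all sulfate libraries lie below 0, in each of the 4 organs.

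The 12 control libraries, sampled 24 h after KCl, show how far the starved organs differed without sulfate. Of 67061 features tested, 23862 were higher and 23504 lower in roots than in the mean of the other organs (limma, Benjamini-Hochberg adjusted p under 0.05). In stem 21294 were higher and 20882 lower, in needles 17610 and 21527, and in cotyledons 24934 and 24861. Differences of at least 16-fold were counted for 538 higher and 548 lower features in roots, 240 and 289 in cotyledons, 405 and 12 in needles, and 50 and 84 in stem. The median absolute log2 difference was 0.52 in roots, 0.41 in stem, 0.35 in needles and 0.59 in cotyledons. Same-numbered libraries of different organs may come from the same pool of seedlings, and the fit treats them as independent.

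The comparison of sulfate with control in roots asks which transcripts of starved roots had changed 1 day after sulfate was supplied. In roots 835 features fell and 294 rose, of 60398 tested (limma, Benjamini-Hochberg adjusted p under 0.05). Most changes were small: the median fall was -0.94 and the median rise 0.61 on the log2 scale, and 759 of the 1129 changed features moved by less than 2-fold. At least 2-fold, 356 fell and 14 rose. The features that fell took 1.70 ± 0.15% of the reads in control roots and 0.908 ± 0.048% in sulfate roots (SD, n = 3), and those that rose took 0.524 ± 0.018% and 0.777 ± 0.025%; both sets were chosen on these libraries. PpCO2_95002 rose from 5.48 ± 1.65 to 27.5 ± 5.4 normalized CPM (SD, n = 3), a log2 change of 2.24 ± 0.21 (SE; limma, Benjamini-Hochberg adjusted p = 0.00468). PpCO2_8510 rose from 0.667 ± 0.562 to 4.34 ± 0.23 normalized CPM, by 2.17 ± 0.33 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.0255). The means of both features were also higher with sulfate in stem, needles and cotyledons, where no change passed. A difference of their effects between organs did not pass (limma F test, Benjamini-Hochberg adjusted p = 0.685 and 0.947). PpCO2_100866 fell from 5.47 ± 2.78 to 0.700 ± 0.426 normalized CPM, a change of -2.28 ± 0.36 (limma, Benjamini-Hochberg adjusted p = 0.0296). PpCO2_136243 fell from 4.54 ± 2.06 to 0.551 ± 0.159 normalized CPM, a change of -2.18 ± 0.31 (limma, Benjamini-Hochberg adjusted p = 0.0183). In each of these features the 3 sulfate values did not overlap the 3 control values, as the rule for naming them required. On recovered reads edgeR called 804 features lower and 248 higher, of which 1027 were shared with limma, and it did not call PpCO2_8510 (edgeR, Benjamini-Hochberg adjusted p = 0.113) or PpCO2_100866 (adjusted p = 0.0585). Leaving out a single library gave 282 (without sulfate 1) to 804 (without control 1) falls and 56 (without sulfate 1) to 375 (without control 1) rises, and ended the call of PpCO2_8510 for 4 of 6 libraries, of PpCO2_100866 for 3 of 6 and of PpCO2_136243 for 3 sulfate libraries.

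In stem the same comparison gave 307 features that fell and 77 that rose, of 58468 tested (limma, Benjamini-Hochberg adjusted p under 0.05). The median fall was -1.90 on the log2 scale, and 244 features fell and 16 rose by at least 2-fold. The features that fell took 0.639 ± 0.088% of the reads in control stem and 0.232 ± 0.007% in sulfate stem (SD, n = 3), and were chosen on these libraries. PpCO2_106664 and PpCO2_106665, which belong to a run of 10 neighbouring identifiers with correlated levels, had the largest falls by the naming rule. PpCO2_106665 fell from 86.9 ± 20.4 to 2.27 ± 0.44 normalized CPM (SD, n = 3), a log2 change of -4.96 ± 0.20 (SE; limma, Benjamini-Hochberg adjusted p = 0.000792). PpCO2_106664 fell from 68.6 ± 16.6 to 1.68 ± 0.48 normalized CPM, a change of -4.98 ± 0.23 (limma, Benjamini-Hochberg adjusted p = 0.000978). PpCO2_154790 rose from 12.2 ± 2.8 to 33.2 ± 2.9 normalized CPM, by 1.43 ± 0.15 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.0129). PpCO2_186464 had 0 reads in all 3 control stem libraries and a mean of 2.23 ± 1.00 normalized CPM with sulfate, at least 78.4-fold higher than the mean level of 3 reads in a control library (limma, Benjamini-Hochberg adjusted p = 0.0161). It also had 0 reads in the control libraries of the other organs, and means of 1.17 ± 1.01 in sulfate roots, 0.618 ± 0.0999 in sulfate needles and 0.352 ± 0.453 in sulfate cotyledons, where it did not reach the filter. Of the sulfate libraries, sulfate 2 was lowest in roots (0.161), stem (1.12) and cotyledons (0) but not in needles (0.683). Same-numbered libraries may share seedlings, so the other organs are not separate support. Leaving out a single library gave 79 (without control 1) to 255 (without sulfate 1) falls and 10 (without control 1, sulfate 2 or sulfate 3) to 63 (without sulfate 1) rises. It ended the call of PpCO2_154790 for 4 of 6 libraries and that of PpCO2_186464 for each control library.

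In needles 281 features fell and 21 rose, of 58847 tested (limma, Benjamini-Hochberg adjusted p under 0.05). The falls were large, with a median of -2.34 on the log2 scale, and 269 of the 281 were at least 2-fold; 15 of the 21 rises were. The features that fell took 0.681 ± 0.108% of the reads in control needles and 0.141 ± 0.008% in sulfate needles (SD, n = 3), and were chosen on these libraries. PpCO2_136231 fell from 26.2 ± 8.7 to 0.247 ± 0.125 normalized CPM (SD, n = 3), a log2 change of -5.13 ± 0.24 (SE; limma, Benjamini-Hochberg adjusted p = 0.000185). It lies in a run of 8 correlated neighbours that also holds PpCO2_136229 and PpCO2_136234, named below for cotyledons. PpCO2_52659 fell from 16.1 ± 6.4 to 0.115 ± 0.073 normalized CPM, a change of -4.69 ± 0.27 (limma, Benjamini-Hochberg adjusted p = 0.000406). PpCO2_154787 rose from 6.30 ± 1.52 to 17.3 ± 1.1 normalized CPM, by 1.41 ± 0.16 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.00798). PpCO2_154790 rose from 3.50 ± 0.95 to 9.51 ± 1.41 normalized CPM, by 1.34 ± 0.19 (limma, Benjamini-Hochberg adjusted p = 0.0271). The summed level of features at least 32 times higher in roots than in needles was 250 ± 31 normalized CPM in control and 203 ± 5 in sulfate needles (SD, n = 3), with no overlap. The like sum for cotyledons was 39.0 ± 18.7 in control and 18.98 ± 4.91 in sulfate needles, and these values overlapped. The needle libraries also differed along a line other than treatment: a split of control 1, sulfate 1 and sulfate 2 from the other 3 gave 6275 features, against 302 for treatment, and with that split as a factor 330 features fell and 59 rose (limma, Benjamini-Hochberg adjusted p under 0.05). Leaving out a single library gave 104 (without control 2) to 315 (without sulfate 3) falls and 2 (without control 2) to 70 (without sulfate 3) rises, and ended the call of PpCO2_154790 for 5 of 6 libraries and of PpCO2_154787 for control 1 and sulfate 1.

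In cotyledons 157 features fell and 9 rose, of 54944 tested (limma, Benjamini-Hochberg adjusted p under 0.05). A single fit over 24 libraries, which pools the spread of all organs, gave 316 falls and 200 rises, so the small share of rises depends on the fit. The median fall was -2.12 on the log2 scale and 151 of the 157 falls were at least 2-fold. The features that fell took 0.373 ± 0.035% of the reads in control cotyledons and 0.0909 ± 0.0096% in sulfate cotyledons (SD, n = 3), and were chosen on these libraries. PpCO2_136229 fell from 69.2 ± 8.8 to 4.30 ± 0.23 normalized CPM (SD, n = 3), a log2 change of -3.86 ± 0.11 (SE; limma, Benjamini-Hochberg adjusted p = 0.000173). PpCO2_136234, in the same run of 8 correlated neighbours, fell from 62.3 ± 6.9 to 4.04 ± 0.45 normalized CPM, a change of -3.79 ± 0.11 (limma, Benjamini-Hochberg adjusted p = 0.000173). PpCO2_141141 rose from 0.480 ± 0.059 to 4.71 ± 1.71 normalized CPM, by 2.37 ± 0.23 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.0126). PpCO2_171977 rose from 0.585 ± 0.155 to 4.15 ± 1.78 normalized CPM, by 2.04 ± 0.27 (limma, Benjamini-Hochberg adjusted p = 0.0477). This feature stood at 242 ± 15 normalized CPM in control roots and 224 ± 14 in control stem. Features at least 32 times higher in roots than in cotyledons summed to 416 ± 14 normalized CPM in control and 517 ± 83 in sulfate cotyledons (SD, n = 3), and the like sum for stem was 501 ± 20 and 658 ± 127, both with no overlap. For PpCO2_171977 limma's adjusted p (Benjamini-Hochberg; edgeR's for 1 of them) ran from 1.36e-07 to 0.253 over 12 alternatives and passed in 4, and the call of PpCO2_141141 ended without any single control library. Leaving out a single library gave 43 (without control 1) to 177 (without sulfate 3) falls and 0 (without control 1 or control 3) to 4 (without sulfate 3) rises by limma (2082 and 1621 higher at an unadjusted p under 0.05 where there were 0), against 113 falls and 3 rises by edgeR with all libraries.

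**Figure D2:**
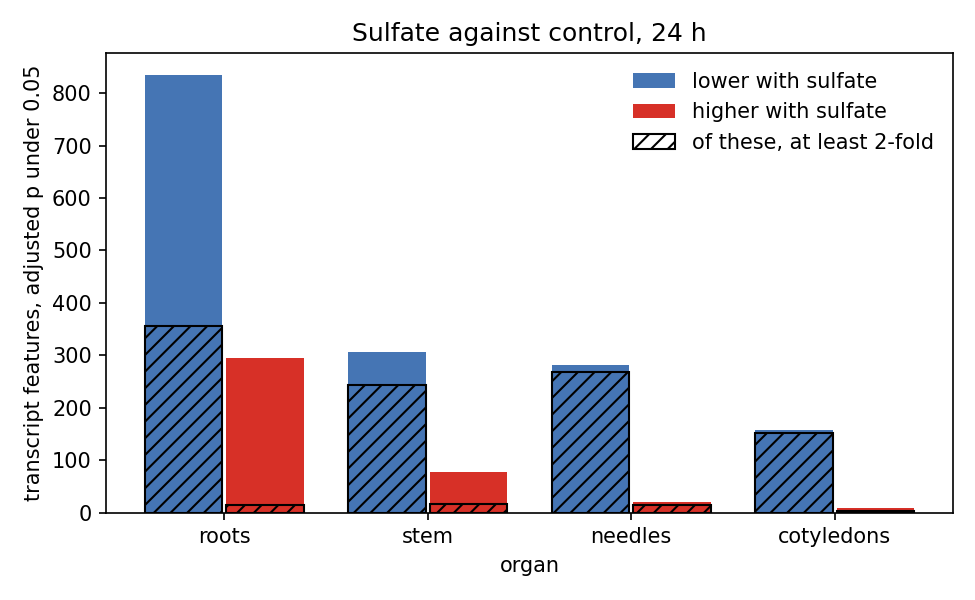
Number of transcript features lower (blue) and higher (red) with sulfate in each organ at an adjusted p under 0.05 by limma, with the part that moved by at least 2-fold hatched (vertical axis: features; 3 libraries a group). Falls outnumber rises in every organ, from 835 against 294 in roots to 157 against 9 in cotyledons.

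Averaged over the 4 organs of the same treatment and replicate number, which gives 3 values a treatment and does not assume that these organs share seedlings, 304 features fell and 65 rose of the 47248 that passed the filter in every organ (limma, Benjamini-Hochberg adjusted p under 0.05). The median fall was -1.59 on the log2 scale, and 230 features fell and 4 rose by at least 2-fold. PpCO2_136231 fell by 3.75 ± 0.27 on the log2 scale (SE; limma, Benjamini-Hochberg adjusted p = 0.00155). Its run also holds PpCO2_136229 and PpCO2_136234, named for cotyledons, so these falls are not independent. PpCO2_156042 fell by 3.46 ± 0.19 (limma, Benjamini-Hochberg adjusted p = 0.000516), from 15.2 ± 4.5 to 0.172 ± 0.044 normalized CPM in needles and from 9.56 ± 1.99 to 2.50 ± 0.61 in roots (SD, n = 3). PpCO2_154787 rose by 1.12 ± 0.13 (limma, Benjamini-Hochberg adjusted p = 0.0164) and PpCO2_154790, in the same run of 9 correlated neighbours, by 1.06 ± 0.12 (adjusted p = 0.013). Falls numbered 255 (without sulfate 2) to 292 (without control 1) when a replicate number of a treatment was left out, and rises 12 (without sulfate 2) to 43 (without sulfate 1). Without such a number limma's adjusted p for PpCO2_154787 passed in 1 of 6 cases and for PpCO2_154790 in 3 of 6.

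The overlap of these lists asks how far the organs shared a response. Of 275 features that fell in needles and 157 that fell in cotyledons among those tested in both, 151 were shared, against 0.81 for independent lists. Stem and needles shared 220 falls (1.42 for independent lists), stem and cotyledons 142 (0.866), roots and stem 227 (3.84), roots and needles 209 (3.13), and roots and cotyledons 131 (1.88). The highest of the 6 adjusted p was 1.33e-233 (one-sided Fisher's exact test, Benjamini-Hochberg over 12 tests; limma lists). The lists of rises were shorter, at 9 to 221 features, and sharing of rises was not tested against sharing of falls. Roots and stem shared 10 rises (0.268 for independent lists; Fisher's exact test on limma lists, Benjamini-Hochberg adjusted p = 2.94e-13) and roots and needles 7 (0.079; adjusted p = 1.42e-12). Stem and needles shared 3 (0.023; Fisher's exact test on limma lists, Benjamini-Hochberg adjusted p = 2.17e-06) and stem and cotyledons 1 (0.00949; adjusted p = 0.0113). Roots and cotyledons shared 0 rises (0.0363 for independent lists), as did needles and cotyledons (0.00355). Features are not independent and same-numbered libraries of different organs may share seedlings, so these p-values are too small. The covariance of log2 fold changes across 47248 features was 0.0261 to 0.0538 over the 6 pairs of organs, above the highest of 9 other splits of the 6 treatment and replicate numbers in each pair (0.0111 to 0.0239). The rank correlation was 0.086 to 0.453 and exceeded every other split only for stem with needles (0.453 against at most 0.384) and roots with cotyledons (0.282 against at most 0.270).

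Among the 47248 features tested in every organ, 120 fell in all 4, 86 in 3, 54 in 2 and 403 in 1, and none fell in an organ and rose in another (limma, Benjamini-Hochberg adjusted p under 0.05 in each). Of the rises, 3 were called in 3 organs, 10 in 2 and 235 in 1. The 120 features that fell in every organ lie in 40 runs of neighbouring identifiers. Their median log2 change was -1.25 in roots, -2.51 in stem, -2.68 in needles and -2.21 in cotyledons. Together they stood at 1555 ± 100.9 plain CPM in control roots and 548 ± 43 in sulfate roots (SD, n = 3). The sums in plain CPM were 1827 ± 380 and 263 ± 15 in stem, 3220 ± 446 and 539 ± 13 in needles, and 3176 ± 303 and 741 ± 85 in cotyledons. The set was chosen on these libraries, so its direction is not independent evidence. Of the 144 falls called in cotyledons, 1 was called in no other organ, against 343 of 579 in roots, 40 of 280 in stem and 19 of 246 in needles. The number that fell in every organ was 39 without stem control 1 or cotyledon control 1 and 131 without cotyledon sulfate 3, and 30 with 1 feature kept per run.

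**Figure D3:**
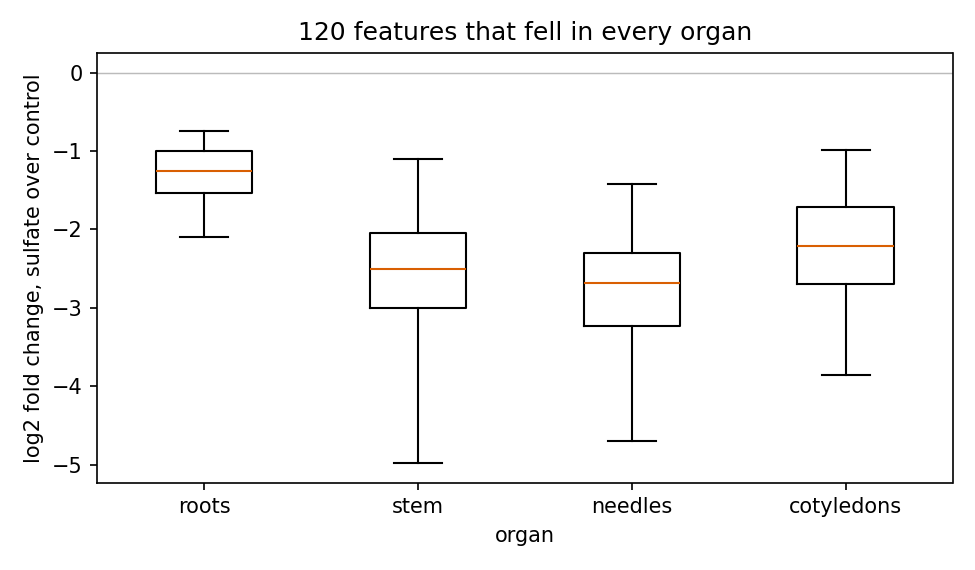
Log2 fold changes, sulfate over control, of the 120 features that fell in every organ, by organ (boxes are quartiles with the median in orange, whiskers the full range). The median is -1.25 in roots and between -2.21 and -2.68 in the other organs.

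Whether the response differed between organs was tested directly. The treatment effect differed by organ for 126 of 47248 features (limma F test of the interaction, Benjamini-Hochberg adjusted p under 0.05). This fit treats same-numbered libraries of different organs as independent, and with the replicate block 201 features passed. By pairs, 132 differed between roots and needles, 68 between roots and stem, 34 between roots and cotyledons, 13 between stem and cotyledons, 9 between stem and needles and 9 between needles and cotyledons. Of the 120 features that fell in every organ, 76 passed the F test, and 75 fell less in roots than in needles, 48 less than in stem and 15 less than in cotyledons, all past the threshold of the test of the pair (limma, Benjamini-Hochberg adjusted p under 0.05); in these pairs no difference the other way passed. Counting fitted values without a test, the fall was smaller in roots than in needles for 118 of the 120, than in stem for 117 and than in cotyledons for 115. The 120 were chosen by passing in each organ, which asks for larger falls where the error is larger. The median SE was 0.132 in needles and 0.121 in cotyledons, against 0.0957 in roots and 0.0906 in stem. How far this choice made the falls in roots look smaller was not tested. PpCO2_106665 fell in all organs but furthest in stem, to 2.27 ± 0.44 normalized CPM, against 25.1 ± 1.6 in sulfate roots, 65.7 ± 3.0 in sulfate needles and 48.4 ± 5.7 in sulfate cotyledons (SD, n = 3). Its log2 change was -2.02 in roots, -4.96 in stem, -2.26 in needles and -2.71 in cotyledons, and its effect differed between organs (limma F test, Benjamini-Hochberg adjusted p = 3.66e-07). PpCO2_136229 fell in every organ, with log2 changes of -1.75 in roots, -3.52 in stem, -4.36 in needles and -3.86 in cotyledons, and its effect differed between organs (limma F test, Benjamini-Hochberg adjusted p = 0.000222). PpCO2_136231 fell in roots (-1.74), stem (-4.17) and needles (-5.13), and its change of -3.95 in cotyledons did not pass there; the difference between organs did not pass either (limma F test, Benjamini-Hochberg adjusted p = 0.074). Leaving out a single library moved the number past the F test to between 67 (without root sulfate 2) and 405 (without needle sulfate 3), and the number for roots against needles to 1194 and for needles against cotyledons to 1140 without needle sulfate 3.

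**Figure D4:**
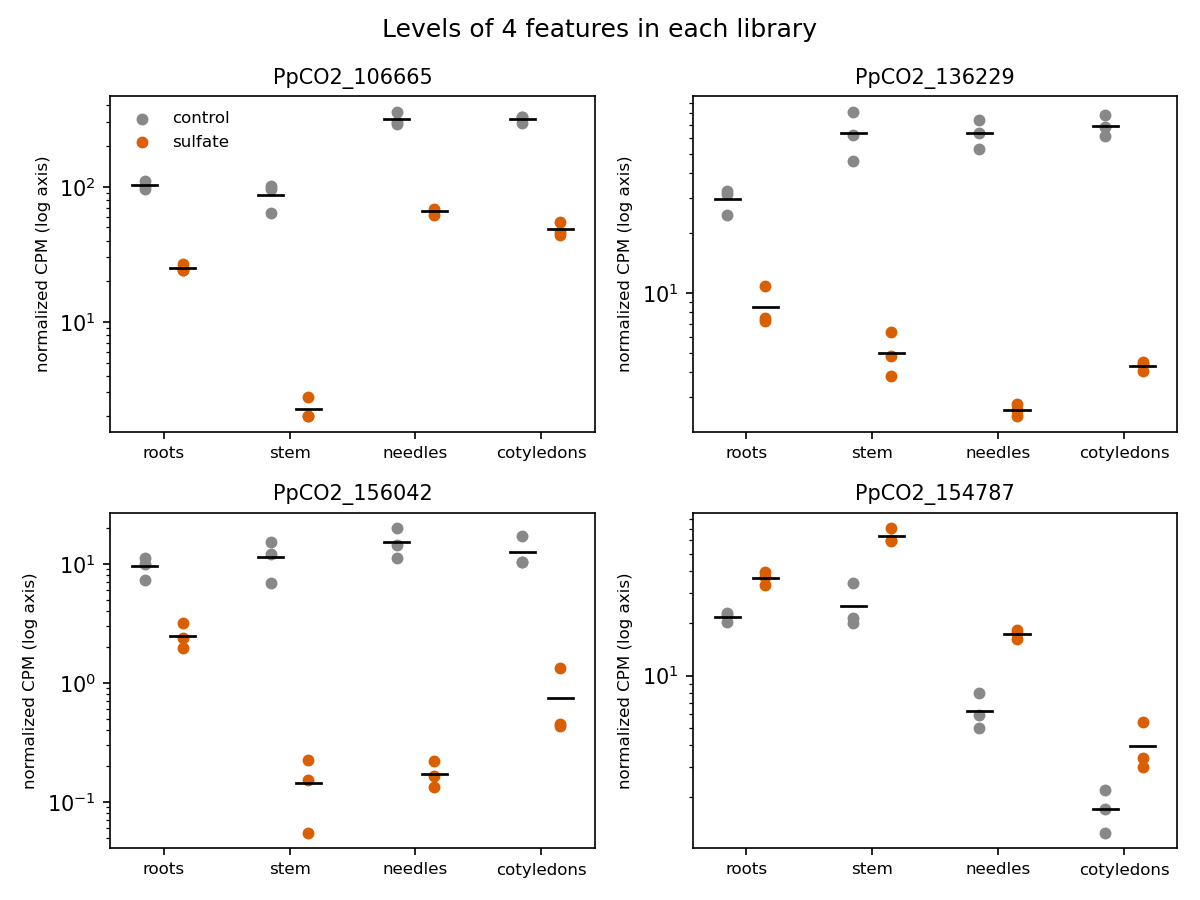
Level of 4 features in each library on a log axis in normalized CPM, by organ and treatment (points are libraries, bars means of 3). PpCO2_106665 drops furthest in stem, to 2.27; PpCO2_136229 and PpCO2_156042 drop least in roots; and PpCO2_154787 has its control and sulfate values apart in each organ, with the change past the threshold in roots and needles.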

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

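The tests of depth, of replicate spread, of starting level and of the needle split (except that of scaling) were chosen after the results were seen. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split was the highest of the 10 (1 of 10) in roots (1129 features against at most 3 for another split), stem (384 against 2), cotyledons (166 against 2) and the average over organs (369 against 2). In needles 2 of 10 splits gave at least the 302 features of the real split, with 6275 for the highest other, and for the interaction F test 2 of 10 splits of the 6 treatment and replicate numbers did, with 740 against 126. For the organ contrasts 1 of 100 splits, the real one, reached 178474 features summed over the 4 contrasts, against 37100. Chance is unlikely there, although 100 splits cannot exclude it.

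The treatment effect differed between organs for 126 features by limma's interaction F test (Benjamini-Hochberg adjusted p under 0.05), among them 7 of those named. Most named features were picked for a large change in an organ of these same libraries, which favours their passing. The fit also pools the spread of all organs and treats same-numbered libraries of different organs as independent. PpCO2_106665 (adjusted p = 3.66e-07) and PpCO2_106664 (adjusted p = 1.33e-06; limma F test, Benjamini-Hochberg) had log2 changes of -4.96 and -4.98 in stem and of -2.02 and -1.99 in roots. PpCO2_136229 (adjusted p = 0.000222) and PpCO2_136234 (adjusted p = 0.000368; limma F test, Benjamini-Hochberg) fell furthest in needles, by log2 changes of -4.36 and -4.37, against -1.75 and -1.73 in roots. PpCO2_52659 (adjusted p = 0.00801) and PpCO2_156042 (adjusted p = 0.00784; limma F test, Benjamini-Hochberg) had log2 changes of -4.69 and -4.51 in needles and of -1.57 and -1.74 in roots. PpCO2_171977 (limma F test, Benjamini-Hochberg adjusted p = 0.000294) changed by 2.04 in cotyledons and by -0.01 in roots, and its call in cotyledons was lost in 8 of 12 alternatives.

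Roots had the most calls, 1129 against 384 in stem, but the fewest large falls. Falls of at least 4-fold numbered 10 in roots, 139 in stem, 187 in needles and 92 in cotyledons. Greater depth is argued against: the median of reads in root libraries was 0.969 times that of the other libraries. Several features per locus are argued against as well, as far as runs of neighbours mark loci, since with 1 feature per run of neighbours roots still had 3.12 times the calls of the next organ. A smaller spread between replicates may account for the gap to needles and cotyledons, because the spread of effects after subtracting sampling variance was 0.861 times the larger of theirs (SD of 0.159 to 0.201 in roots and 0.145 to 0.291 in needles with a library left out, ranges that overlap). For stem it cannot be told apart: the median residual SD of roots was 1.06 times that of stem, and 0.943 to 1.13 with each of the 12 libraries left out.

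The 120 features that fell in every organ had their smallest median fall in roots, although single features among them fell more there. Compression by the pseudocount is argued against, as with a pseudocount of 0.1 the median in roots was still 1.27 log2 units above that of the organ with the next smallest fall. Less room to fall in roots is argued against by the median levels. The lowest of the 3 medians in sulfate roots was 0.142 normalized CPM above the highest in any other sulfate library. However, the summed level in plain CPM was higher in sulfate cotyledons, and sums in normalized CPM were not compared. Reads of unlike copies merged in a feature were not tested. Nor was the choice of features by a call in each organ, which asks for larger falls where the error is larger. That roots, the organ that meets the sulfate, may keep more of these transcripts or may have been at another stage of the response at 24 h is a hypothesis that a single time point cannot test.

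Needle libraries parted on a line other than treatment: control 1, sulfate 1 and sulfate 2 against control 2, control 3 and sulfate 3 gave 6275 features (2714 higher, 3561 lower), which points to a structure of these samples, and the same split of replicate numbers gave 740 features in the interaction test. Seedling pools that differ as a whole, if organs of a number share them, are argued against, since the same split of numbers gave 0 features in roots, stem or cotyledons by limma (2925, 2128 and 2259 at an unadjusted p under 0.05). The authors' scaling is argued against, since after rescaling the split gave 6567. RNA of another organ cannot be settled here. Of the features called, 99.9% shifted by more than the measured share of other organs' RNA, at most 3.02% in a single needle library, would give. That share comes from features at least 32 times higher in the other organ, a choice that keeps it low. Of these, 10 of cotyledons moved with the split by a median of -0.83 (3 called lower, 0 higher, by limma), 15 of stem by -0.22 and 33 of roots by 0.02. Across features the shift had a Spearman correlation with the organ difference of -0.368 for roots, -0.147 for stem and 0.214 for cotyledons. A difference in needle age, sampling or handling stays open too, untested. With the split as a factor 298 of the 302 treatment calls, which were chosen on these libraries, remained.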

How the results depend on the processing

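Keeping 1 feature per run, the needle split as a factor, moderation without the trend and robust options, and all alternatives for the features that fell in every organ were added after the data were seen. Falls outnumbered rises in each organ under every alternative with an adjusted p under 0.05. At an unadjusted p under 0.01 rises outnumbered falls in cotyledons (663 against 510 among features tested also in needles), and stem went either way (962 against 930 among those tested also in needles, 864 against 903 among those tested also in cotyledons). The lowest share of falls with 1 feature per run was 72.8% and with rescaling 75.4%, both in roots. Pseudocounts and rescaling moved no count of an organ by over 1.5 times. A minimum of 5 in place of 1 tests fewer features and left 542 falls in roots, 196 in stem, 183 in needles, 86 in cotyledons (4 rises) and 50 in every organ. A fold of at least 2, a stricter criterion, left 356 falls and 14 rises in roots, 16 rises in stem and 3 in cotyledons. With 1 feature per run there were 327 falls and 122 rises in roots, 115 and 29 in stem, 111 and 5 in needles, 44 and 1 in cotyledons, and 30 falls in every organ. Without the trend and robust options roots had 545 falls and 163 rises. With edgeR cotyledons had 3 rises. A single fit over 24 libraries pools the spread of all organs and gave 120 rises in stem, 505 falls and 249 rises in needles, 316 and 200 in cotyledons and, as an equal-weight average that counts organs of a number as independent, 1535 and 1221. Its share of falls was 67.0% in needles against 93.0%, and 61.2% in cotyledons against 94.6%. The needle split as a factor gave 59 rises in needles. An unadjusted p under 0.01 gave 207 falls in every organ, and shared falls of 439 (roots and stem), 358 (roots and needles), 294 (roots and cotyledons), 353 (stem and needles), 245 (stem and cotyledons) and 280 (needles and cotyledons). Shared rises were then 142, 70, 109, 97, 58 and 64 in that order. For differences of effect, a pseudocount of 2 gave 32 features for roots and stem, 4 for stem and cotyledons and 0 for needles and cotyledons (limma; 3940 at an unadjusted p under 0.05), and a pseudocount of 0.1 gave 20 and 14 for the last pairs. Apart from fewer features tested, a stricter criterion or pooled spread, the cause was not tested.

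Replicate numbers are not described as pairing libraries. Between treatments of an organ, deviations of same-numbered libraries correlated over 0.1 in 6 of 12 pairs (-0.415 to 0.364), and 14 of 24 libraries correlated best with their own number. Between organs of a treatment 34 of 36 pairs did (-0.017 to 0.463), and all 24 correlated best with their own number, a hint from the data that organs of a number share a pool. With the replicate block there were 44 rises in stem, 40 in needles and 25 in cotyledons, 103 rises in the average, 201 features past the F test, 204 for roots and needles, 88 for roots and cotyledons, 22 for stem and cotyledons and 16 for needles and cotyledons. The block moved no other count by over 1.5 times and ended the call of PpCO2_171977.

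Leaving out a library keeps 2 in a group and leaves less to estimate the error from, although some counts rose. It also drops features under 1 in the other group, which then lack the 3 libraries the filter asks for. Falls ranged over 282 to 804 in roots (moved by over 1.5 times without control 2 or 3 or sulfate 1 or 2), 79 to 255 in stem (any library but sulfate 1), 104 to 315 in needles (any control), 43 to 177 in cotyledons (any but sulfate 3) and 255 to 292 in the average. Rises ranged over 56 to 375 in roots (without control 2 or any sulfate library), 10 to 63 in stem (any but sulfate 1), 2 to 70 in needles (any), 0 to 4 in cotyledons (any) and 12 to 43 in the average (any replicate number). Falls in every organ ranged over 39 to 131, moved by any control of stem, needles or cotyledons and by cotyledon sulfate 1. The F test gave 67 to 405, moved by root control 2 and 3, root sulfate 1 and 2, needle sulfate 3 (405) and cotyledon control 2 (190). Differences ranged over 21 to 84 for roots and stem (moved by root control 2 and 3, root sulfate 1 and 2, stem control 1 and 2, stem sulfate 2 and 3), 94 to 1194 for roots and needles and 8 to 26 for stem and needles (needle sulfate 3), 12 to 106 for roots and cotyledons (root control 2, any root sulfate, any cotyledon library but control 1), 11 to 54 for stem and cotyledons (cotyledon control 2 and sulfate 3) and 2 to 1140 for needles and cotyledons (16 of 24 libraries). For the organ contrasts no library moved a count by over 1.5 times. Of 174 values of named features under other settings 164 kept their call and 10 lost it, and of 102 with a library left out 64 kept it and 38 lost it; none turned direction. Over the alternatives in which a feature was tested, adjusted p (limma or edgeR, Benjamini-Hochberg) stayed under 0.05 for each named fall but PpCO2_100866 and PpCO2_136243, and among named rises for PpCO2_95002. Cases in which a feature dropped out of the test are not counted here. PpCO2_136231 and PpCO2_52659 dropped out in needles when any needle control was left out. Gene list tests were not run, as the files pair no names. Depth sets a floor of at most 0.0351 normalized CPM per library, under the filter of 1; whether depth or the number of libraries limits the calls was not tested.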

Other observations

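The tests of features that follow a replicate number, of the order of the list and of RNA from other organs were chosen after the data were seen. Neighbouring identifiers behaved alike: levels of 47662 pairs of neighbours correlated across the 24 libraries with a median Pearson r of 0.879, against 0.040 for random features of like level, and features are not independent replicates. A hypothesis is that neighbouring numbers mark related transcripts, such as forms or copies of a gene. In the 25957 pairs with a tested sulfate effect, the effects averaged over organs differed by a median of 0.0506 log2 units. The median was 0.0993 for random features, a difference of -0.0487. The hypothesis would give such a difference, but this does not tell related transcripts from reads shared between copies. The 67271 features fell into 35682 runs, and the 835 features that fell in roots into 515 runs, against a median of 822 for random sets of that size. In stem 307 falls lay in 140 runs, in needles 281 in 129 and in cotyledons 157 in 58. Whether a run is a locus was not tested.

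Levels of some features followed the replicate number of a treatment in every organ. In 23 features the level was at least 8 times lower for 1 number than for the other 2 of its treatment in all 4 organs, against a median of 0 and a maximum of 12 in 100 draws with replicate numbers permuted within organs. A candidate explanation is that organs of a number come from the same pool of seedlings and that pools differ in which alleles or copies they carry, but the labels do not say that organs of a number share a pool. The test was made on the data in which the pattern was seen, and no genotypes were used here. Among the named rises, PpCO2_8510 had few reads in control 1 of roots, stem, needles and cotyledons (13, 9, 1 and 3). PpCO2_141141 had more reads in control 3 of roots, stem and needles (164, 201 and 396) than in control 1 or 2. PpCO2_95002 had its lowest control level in control 3 of each organ, but in roots control 1 was close (4.41 and 4.66 normalized CPM). Whether such differences between replicate numbers enter these rises was not tested.

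The order in which features are listed in the deposited table follows a response to sulfate. The place in the list had a Spearman correlation across features of 0.914 with the p of the sulfate effect in cotyledons in a fit over 24 libraries, against 0.0428 to 0.0734 for the other organs. Of the first 300 listed features, 246 were among the 300 with the lowest p in cotyledons, where 1.34 would be there at random. The like counts were 208 for needles, 194 for stem and 114 for roots, so the top of the list is not particular to cotyledons.

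Features at least 32 times higher in another organ, taken as a measure of RNA from other organs, summed to at most 1.72% of their level in the source organ as a mean over the 6 libraries of an organ. The highest single needle library reached 3.02%, for features of cotyledons. Choosing features at least 32 times higher limits the share they can show. In 3 of 12 pairs of organs these sums did not overlap between treatments, where chance gives 10% of pairs: features of roots and of stem were higher in sulfate cotyledons by 0.31 and 0.39 log2 units, and features of roots lower in sulfate needles (-0.30). The largest shift was that of cotyledon features in needles, from 39.0 ± 18.7 to 18.98 ± 4.91 normalized CPM (SD, n = 3), a log2 change of -1.04 with overlapping values.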
